A study of Rattus norvegicus with 12 samples.

How the data were processed

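Methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq) was applied to rat sperm DNA. In this assay an antibody against methylated cytosine pulls down DNA fragments, so more reads in a stretch of the genome mean more recovered methylated DNA from it, and the reads do not give a methylation percentage per site. Per the labels, the rats were outbred Hsd:Sprague Dawley, the F0 dams were injected with vinclozolin at 100 mg/kg per day or with its vehicle on gestation days 8 to 14, and sperm were collected at 12 months of age. Each of the 12 libraries came from a pool of equal amounts of DNA of 3 rats, and there were 3 pools for each of 4 groups. Groups and pool numbers were taken from the sample titles.

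The deposited data were 1 table for each generation. Per the file headers, the authors gave a read count for each 100-bp window of each library, the RPKM (reads scaled by window length and library depth) of the same window, and a comparison of both lineages by edgeR. The deposited counts were whole numbers that had not been normalised. The authors' RPKM was proportional to the count within a library, and it served here only to infer the number of reads and to check the direction of the authors' fold change. The authors' deposited log2 fold change was of control over vinclozolin, as its sign followed the counts, and is given below with the sign turned to vinclozolin over control. The authors' deposited p-value and adjusted p were present only for windows with at least 10 counts over the 6 libraries of a generation. The submitters' processing notes name FastQC, Bowtie2, SAMtools and edgeR, without versions, and the genome build Rnor_6.0. The column names are those that the MEDIPS package writes. Trimming, handling of reads with several matching places, and duplicate removal are not given in the sources used here. The highest window count was 300 in every library, and each read was counted in 1.5 windows on average, as the ratio of window counts to the reads implied by the RPKM shows. A ceiling of this kind compresses differences at windows of very high coverage.

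Both tables listed the same 27820300 windows on chromosomes 1 to 20, X, Y and MT. Counts of the 10 windows of each consecutive 1-kb tile were summed, which gave 2782040 tiles. The 1026158 tiles with a mean of at least 10 summed counts per library over the 12 libraries were tested; they made up 36.9% of the tiles and held 88.2% of the counts. Of the tested tiles, 18 had a window at the highest count. Since a read can add to more than 1 window, a summed count is not a number of reads. Levels are given as CPM, that is, relative to the summed counts in tested tiles after scaling by TMM (trimmed mean of M values) factors.

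Vinclozolin was compared with control within F1 (6 libraries) and within F3 (6 libraries), and the difference of both effects was tested as an interaction over all 12 libraries. Each test was edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3), two-sided, with TMM factors, Benjamini-Hochberg adjustment over the tested tiles and a threshold of 0.05. To save time, the dispersion trend was estimated on 100000 tiles spaced evenly in rank of abundance and interpolated to the others. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. The tests, the samples in each, the rule for named tiles and most alternatives were fixed before the data were examined. By that rule, adjoining called tiles of the same direction were merged into regions, and the 5 regions of smallest p in each direction are named; where fewer passed, tiles of smallest p that did not pass fill the place, and their values are given as such. For the difference, the 5 tiles of smallest p are named. The distance of 200 kb within which called tiles were joined into a locus was set after the called tiles had been seen.

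Shares of counts and relative levels of whole chromosomes were compared by exact permutation tests of 3 pools against 3, two-sided, for which the smallest possible p is 0.1. Fold changes of both generations were compared across tiles by Spearman's correlation, with 1000 circular shifts of the tiles along the genome as a reference and with all 100 pairs of splits of the pools as another. Overlaps of tile lists were compared with the same circular shifts. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these. Each model was tested on simulated counts drawn from the means and library sizes of the real tiles, with 200 changed tiles. The simulated spread followed the fitted dispersion trend alone. It held no variation of dispersion between tiles of like abundance and no trend of a library with signal level, so recovery in the real data may be lower. With a 4-fold change, 55 of 100 tiles were recovered in the F1 comparison, 53 of 100 in F3 and 11 of 100 for the difference. With a 2-fold change, 0, 3 and 0 of 100 were recovered. False calls numbered 3, 2 and 2.

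The alternatives were other normalisation factors (DESeq2's size factors, and library totals alone), other filters on low counts, the pool number as a block, each pool left out, 1 fit over all libraries, 100-bp windows in place of tiles and other lists for the overlap. Added after seeing the data were edgeR's newer quasi-likelihood method with adjusted deviances, a correction of each library's trend with signal level (lowess span 0.3), that correction together with the block, DESeq2 1.42.0's Wald test, fits without both libraries that lay apart in signal level, and all alternatives for the correlation of fold changes. Chi-square per degree of freedom between libraries of a group ran from 2.24 to 8.98. As reads enter several windows it exceeds 1 by construction, so it cannot tell separate pools from repeat runs of 1 pool. The 12 were counted as separate samples because the labels give each as its own pool.

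Promoter counts, gene lists, named genes, classes of CpG density, the correction for CpG density and the position of tiles relative to genes had been planned. They need an annotation or the sequence of Rnor_6.0, and neither was used here: the gene table at hand lies on another assembly, GRCr8, and its coordinates cannot be set against these. Regions are therefore given by chromosome, start and end (1-based) without genes.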

Results

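The series asked how the sperm DNA methylome of rats differs between a lineage whose founding dams received vinclozolin in pregnancy and a vehicle lineage, and how the F1 generation, exposed in the womb, compares with the F3 generation, the great-grandchildren of the treated dams. Vinclozolin is a fungicide whose breakdown products block the androgen receptor. The groups were F1 control, F1 vinclozolin, F3 control and F3 vinclozolin, each with 3 sperm DNA pools of 3 rats. Total window counts ran from 28838085 in F3 vinclozolin pool 3 to 75942901 in F1 control pool 3. They averaged 55779633 ± 19363036 (SD, n = 3 pools) in F1 control, 65879497 ± 7953749 in F1 vinclozolin, 51638355 ± 15453174 in F3 control and 37150216 ± 8115425 in F3 vinclozolin. The median tested 1-kb tile held 21.9 summed counts per library. Whether the pools of a group drew on separate litters is not given in the sources used here, so the p-values measure the spread between pools.

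The shares of counts along the range of coverage gave no exact permutation p under 0.3, where 3 pools against 3 allow no p under 0.1. Tiles with a mean count of 100 or more held 40.5% ± 10.5 (SD, n = 3) of the counts in F1 control and 38.9% ± 4.13 in F1 vinclozolin, and the exact permutation p was 1. In F3 they held 43.7% ± 1.63 in control and 46.0% ± 7.49 in vinclozolin, with an exact permutation p of 0.9. Over 6 classes of tiles by mean count, the smallest exact permutation p was 0.3 in F1, for the class of 50 to 100 with 14.7% ± 0.541 in control and 14.0% ± 0.278 in vinclozolin, and 0.4 in F3. Single libraries differed more than the groups did: the share was 51.5% in F1 control pool 1, 54.5% in F3 vinclozolin pool 3 and 30.7% in F1 control pool 3.

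**Figure D1:**
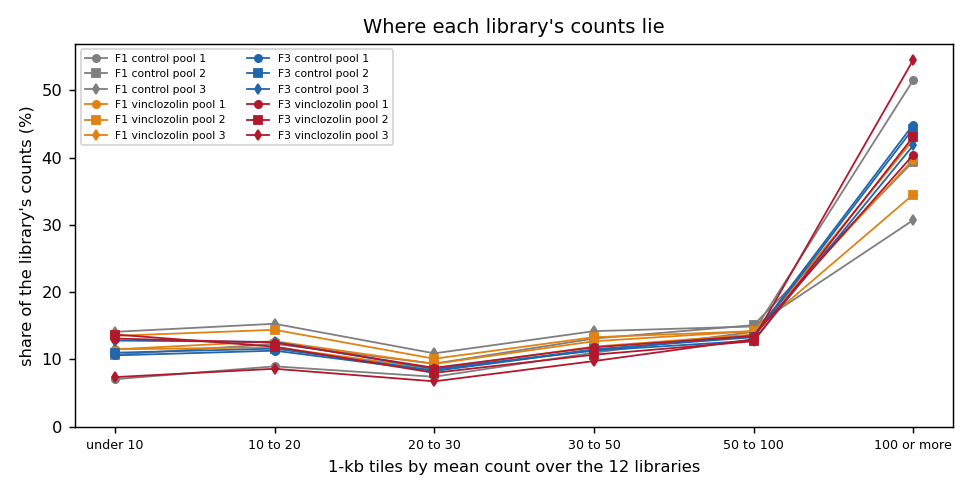
Share of each library's counts (percent, vertical axis) in 1-kb tiles grouped by their mean count over the 12 libraries (horizontal axis), with 1 line per pool, coloured by group. F3 vinclozolin pool 3 at 54.5% and F1 control pool 1 at 51.5% have the highest shares in the class of 100 or more, and F1 control pool 3 at 30.7% the lowest.

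Levels of the 23 chromosomes were set relative to the autosomes. No chromosome had an exact permutation p under 0.2 in F1. In F3, chromosomes 1 and 17 reached 0.1, the smallest p that 3 pools against 3 allow; the adjusted p was 0.92 for both. Chromosome 1 stood at 1.05 ± 0.00567 in control and 1.08 ± 0.0156 in vinclozolin (SD, n = 3), and chromosome 17 at 1.01 ± 0.00242 and 0.997 ± 0.0118. For the difference between generations the smallest adjusted p of the permutation test over the chromosomes was 0.6133. The mitochondrial level spread within groups, with 4.13 ± 5.76 in F1 control and 5.10 ± 2.16 in F1 vinclozolin (exact permutation p = 0.8).

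In F1 sperm, no 1-kb tile passed the threshold for a difference between the vinclozolin and control lineages. Of 1026158 tested tiles, edgeR's quasi-likelihood test called 0, and 34351 had an unadjusted p under 0.05, which is fewer than 1 in 20. DESeq2's Wald test also called 0, with 20481 at an unadjusted p under 0.05. The tile of smallest p was on chromosome 10 from 75054001 to 75055000, at 2.10 ± 0.228 CPM in control and 0.727 ± 0.115 in vinclozolin (SD, n = 3). Its log2 fold change was -1.54 (SE 0.27), with an edgeR adjusted p of 1. A second tile on the same chromosome, from 75180001 to 75181000, had 1.42 ± 0.207 CPM in control and 0.507 ± 0.103 in vinclozolin, a log2 fold change of -1.49. On the higher side, the tile of smallest p was on chromosome 2 from 208717001 to 208718000, with 0.288 ± 0.0734 CPM in control and 0.957 ± 0.151 in vinclozolin and a log2 fold change of 1.75 (SE 0.33). The tile on chromosome 14 from 101988001 to 101989000 followed with 0.450 ± 0.235 and 1.59 ± 0.327 CPM.

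The other F1 tiles of smallest p did not pass either. Higher values in vinclozolin were measured at chromosome 2 from 159039001 (log2 1.37), chromosome 6 from 19211001 (log2 1.87) and chromosome 3 from 103236001 (log2 1.28). Lower values were measured at chromosome 15 from 51672001 (log2 -1.42), chromosome 2 from 55921001 (log2 -1.52) and the X chromosome from 40667001 (log2 -2.11). In all 10 of these tiles the 3 vinclozolin pools lay beyond the 3 control pools, which chance gives for 10% of tiles, and the tiles were picked by p. In simulated data the same F1 test recovered 55 of 100 tiles with a 4-fold change and 0 of 100 with a 2-fold change. The simulated spread followed the dispersion trend alone, so recovery in the real data may be lower. Without F1 control pool 1, and likewise without F1 control pool 3, 1 tile was called.

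In F3 sperm, 19 tiles changed, and each was higher in the vinclozolin lineage. They formed 11 regions at 6 loci, and 16 of the 19 lay in 3 loci on chromosomes 1, 14 and 5. Fold changes ran from 3.28 to 16.7, with a median log2 fold change of 2.44. In all 19 the 3 vinclozolin pools were above the 3 control pools, while chance sets 3 pools apart from 3 in either direction for 10% of tiles; the 19 were called on these same values. No tile was called lower, although several of the alternatives given below called lower tiles too. At an unadjusted p under 0.05 there were 56010 tiles.

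The region of smallest p was on chromosome 1 from 11910001 to 11914000, with 4 called tiles. Its leading tile, from 11911001 to 11912000, had 0.553 ± 0.401 CPM in F3 control and 4.56 ± 1.81 in F3 vinclozolin (SD, n = 3). The log2 fold change was 3.02 (SE 0.35) and the edgeR adjusted p was 4.6e-05. This tile was called in 15 of its 16 alternatives; the exception was DESeq2's Wald test, run after seeing the data, with a log2 fold change of 3.06 and an adjusted p of 0.31, the highest over the alternatives (range 4.3e-16 to 0.31). The second region lay on the same chromosome, from 11964001 to 11966000, and its leading tile from 11965001 to 11966000 rose from 0.608 ± 0.306 to 3.99 ± 1.83 CPM (log2 2.68, SE 0.32, edgeR adjusted p = 0.00011). On chromosome 7 the tile from 27563001 to 27564000 rose from 0.0667 ± 0.0627 to 1.33 ± 0.657 CPM (log2 4.06, SE 0.51, edgeR adjusted p = 0.00016). On chromosome 14 the region from 46637001 to 46640000 rose, led by the tile from 46637001 to 46638000 with 0.577 ± 0.310 and 3.47 ± 1.49 CPM (log2 2.58, SE 0.32, edgeR adjusted p = 0.00016). On chromosome 5 the region from 91127001 to 91129000 rose, led by the tile from 91127001 to 91128000 with 0.718 ± 0.425 and 3.83 ± 1.32 CPM (log2 2.39, SE 0.32, edgeR adjusted p = 0.00036). Some of these calls were lost when 1 pool was left out, with the fold changes given here. The chromosome 5 tile was called in 13 of 16 alternatives (adjusted p from 6.7e-10 to 0.091), and lost its call without F3 control pool 1 (log2 2.03, adjusted p = 0.091), vinclozolin pool 2 (log2 2.09, adjusted p = 0.051) or control pool 3 (log2 2.46, adjusted p = 0.05). The chromosome 7 tile was called in 14 of 15 (adjusted p from 1.3e-11 to 0.058, the highest without vinclozolin pool 2, at log2 3.64) and the chromosome 14 tile in 15 of 16 (adjusted p from 5.2e-11 to 0.051, the highest without control pool 1, at log2 2.30). The second chromosome 1 tile was called in 16 of 16.

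**Figure D2:**
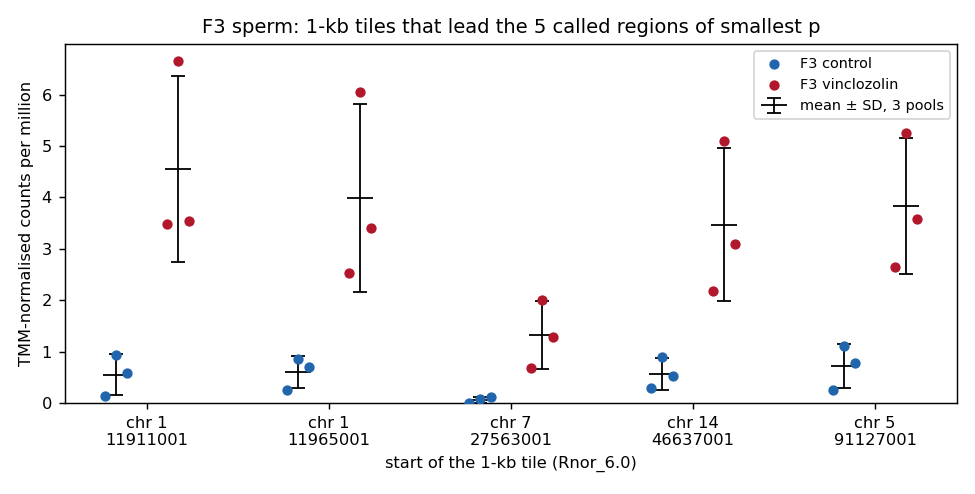
TMM-normalised CPM (vertical axis) of the F3 control and F3 vinclozolin pools at the leading 1-kb tile of the 5 called regions of smallest p (horizontal axis, chromosome and start). Points are pools and black marks are the mean ± SD of 3 pools; at the first tile the means are 0.553 and 4.56, and in each tile the vinclozolin pools lie above the control pools.

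The remaining 6 regions were 3 on chromosome 14 (46580001 to 46581000, 46635001 to 46636000 and 46680001 to 46682000), and 1 each on chromosome 5 (91125001 to 91126000), chromosome 9 (98050001 to 98051000) and chromosome 16 (19110001 to 19111000). Their log2 fold changes lay between 1.71 and 2.71. The loci on chromosomes 1, 14 and 5 lie in stretches of very high coverage: the highest tile within 20 kb held a mean of 1930, 1650 and 506 counts, against 21.9 for the median tested tile. Of the called tiles, 16 of 19 (84.2%) lay within 20 kb of a tile with a mean count of 500 or more, against 4.36% of tested tiles. This distance and count were chosen after the loci had been seen, and the 16 tiles belong to 3 loci, so no test is given. On the lower side, no tile passed. The tile of smallest p, on chromosome 8 from 99448001 to 99449000, had 1.12 ± 0.211 CPM in control and 0.303 ± 0.0346 in vinclozolin (log2 -1.85, edgeR adjusted p = 0.19). Values on chromosome 3 from 28319001 (log2 -2.60), chromosome 4 from 165088001 (log2 -1.68), chromosome 3 from 29960001 (log2 -4.80) and chromosome 3 from 37335001 (log2 -1.64) did not pass either.

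**Figure D3:**
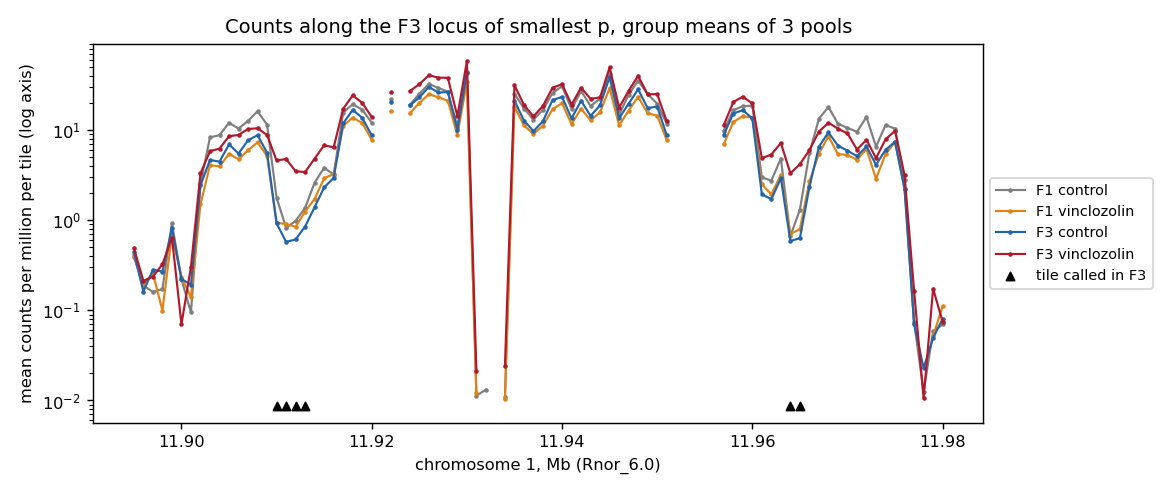
Mean CPM per 1-kb tile (vertical log axis) along the chromosome 1 locus that spans 11910001 to 11966000 with its flanks (horizontal axis, Mb), as group means of 3 pools; triangles mark the 6 tiles called in F3, and tiles at 0 are not drawn. The F3 vinclozolin line lies above the others at the called tiles, which sit in dips beside tiles of high coverage.

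The number of F3 calls changed when single pools were left out. It was 3 without F3 control pool 1, 7 without control pool 3, 8 without vinclozolin pool 2, 61 without vinclozolin pool 3 (51 higher and 10 lower in vinclozolin) and 766 without vinclozolin pool 1 (721 and 45). With 1 fit over all 12 libraries it fell to 13. It rose to 124 with a minimum mean count of 30 (115 higher and 9 lower in vinclozolin), to 127 with no filter (119 and 8) and to 304 for 100-bp windows (279 and 25). With settings chosen after seeing the data it was 204 with adjusted deviances (196 and 8), 185 with the signal-level correction (165 and 20) and 242 with that correction and the pool number as a block (205 and 37).

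For the difference between generations, no tile passed the threshold. edgeR's interaction test over all 12 libraries called 0 of 1026158 tiles, with a smallest adjusted p of 0.069 and 62879 tiles at an unadjusted p under 0.05. DESeq2's Wald test was not run for this comparison. Of the 5 tiles of smallest p, 3 lay in the F3 loci. On chromosome 14 from 46638001 to 46639000 the effect was -0.58 on the log2 scale in F1 and 2.46 in F3, a difference of 3.04 (SE 0.46). On chromosome 1 from 11910001 to 11911000 it was -0.91 and 2.31, a difference of 3.22 (SE 0.50). The tile on chromosome 1 from 11965001 had a difference of 3.37 (SE 0.56). The chromosome 10 tile from 75054001 had -1.54 in F1 and 1.11 in F3, a difference of 2.64 (SE 0.42). On chromosome 4 from 5693001 to 5694000 the values were -0.94 and 1.49, a difference of 2.44 (SE 0.41).

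At the 19 tiles called in F3, the F1 log2 fold changes ran from -0.96 to 1.62, with a median of -0.26, and 15 of the 19 were below 0. The F1 median over all tested tiles was -0.003. As 16 of the 19 lie in 3 loci, they are not separate observations. The count for the difference depended on the setting. It was 219 without F1 control pool 3 (126 with a higher and 93 with a lower effect in F3 than in F1), 3 without F1 control pool 1, 79 with no filter on low counts (57 and 22), 4 with a minimum mean count of 30 and 3 with the pool number as a block. It rose most with settings chosen after seeing the data: 1113 with the signal-level correction (1051 and 62) and 982 with that correction and the block (943 and 39).

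No tile was called in both generations, since none was called in F1. Among the 1000 tiles of smallest p in each generation, 5 were in both, where independent lists give 0.975 and 1000 circular shifts of the tiles gave 0 to 5 (permutation p by circular shifts = 0.006). None of the 5 had the same direction in both generations. Among the 10000 tiles of smallest p, 283 were in both, where independent lists give 97.5 and the shifts gave 65 to 127 (permutation p by circular shifts = 0.001, the smallest they can give), and 23 of the 283 had the same direction. The overlap was not compared with other groupings of the pools, so these p-values do not cover how the pools fell into groups. Across all tested tiles, which are not independent replicates, the F1 and F3 log2 fold changes had a Spearman correlation of -0.132, outside the -0.006 to 0.005 of 1000 circular shifts. It was -0.041 without F1 control pool 1, with the same sign in 49.1% of tiles, and -0.080 without F1 vinclozolin pool 2. Shifts keep the libraries as they are; when the pools of both generations were regrouped in every way, 38 of 100 pairs of splits gave a correlation of mean differences as large in size. The control libraries of both generations were separate.

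The authors' deposited table was also read as it stands. In F1 it lists 2 windows at p under 1e-06 (1 higher and 1 lower in vinclozolin), 28 under 1e-05 and 0 at an adjusted p under 0.05. In F3 the authors' deposited table lists 82 windows at p under 1e-06, of which 70 were higher and 12 lower in vinclozolin, in 67 regions of adjoining windows. Listed windows may not all be separate observations. In F1, those on chromosomes 3 (from 17898301), 6 (from 87759401) and 20 (from 44948501) had the same count in each library. In F3, those on chromosomes 15 (from 18327401) and 10 (from 98727701) had nearly the same counts. The cause was not tested. At the authors' adjusted p under 0.05 there were 64 F3 windows, 54 higher and 10 lower. The window of smallest p in the authors' deposited table for F3 lies on chromosome 19 from 15044801 to 15044900 and was lower in vinclozolin (log2 -1.15, adjusted p = 2.9e-05). The 1-kb tile around it had 10.9 ± 0.717 CPM in F3 control and 5.67 ± 0.499 in F3 vinclozolin (SD, n = 3), with a log2 fold change of -0.95 and an edgeR adjusted p of 0.63. Of the 64 windows, 27 lay within 50 kb of the loci on chromosomes 1, 14 and 5, and 24 lay in a called tile. At p under 1e-05 and under 1e-04, the authors' deposited table has 0 windows in both generations, and at p under 1e-03 it has 6, where independent lists give 4.4.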

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

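The number of called tiles moved with several choices, and the cause was not tested unless stated. For F1, 0 tiles were called, and 0 was also found with DESeq2 size factors, library totals, both other filters, 1 fit over all libraries, 100-bp windows, the signal-level correction, adjusted deviances and DESeq2's test; leaving out each pool gave 0 to 1. For F3, 19 tiles were called. The count was 18 with DESeq2 size factors and 13 with 1 fit over all libraries, all of them among the 19. It was 31 with library totals, 127 with no filter on low counts, 124 with a mean count of at least 30 and 304 for 100-bp windows. With settings chosen after seeing the data it was 204 with adjusted deviances, 185 with the signal-level correction, 242 with that correction and the block, and 19 with DESeq2's Wald test, 15 of them shared. DESeq2's test gave no adjusted p for 497373 of the 1026158 tiles in F3, so its adjustment ran over fewer tiles. All 19 tiles kept a positive fold change in each setting that tested them, and leaving out each pool gave 3 to 766 calls, with 3 to 19 of the 19 among them. For the difference, 0 tiles were called, and the count was 79 with no filter and 4 with a mean count of at least 30. After seeing the data it was 2 with adjusted deviances, 1113 with the signal-level correction, 982 with that correction and the block, and 5 without both libraries apart in signal level; leaving out each pool gave 0 to 219. Library totals moved the median log2 difference of all tiles from -0.007 to -0.11. The pool numbers are shared between lineages. Over all tested tiles, same-numbered pools did not deviate together (correlations of deviations of 0.15, -0.04 and -0.24 in F1, and -0.08, 0 and -0.09 in F3). At the F3 loci on chromosomes 1, 14 and 5, however, pool 1 was lowest and pool 2 highest in both F3 lineages. With the block, the edgeR adjusted p of the chromosome 1 tile from 11911001 was 7.5e-08 against 4.6e-05. The smaller adjusted p follows from that same order of pools. The loci share 1 order, so these are not separate signs of pairing. Whether the numbers pair the samples thus stays open. Over all tested tiles, no control pool of either generation correlated best with the vinclozolin pool of its own number. Seen from the vinclozolin pools, only F1 vinclozolin pool 1 did. With the pool number as a block the counts were 0 in F1, 23 in F3 (17 of the 19 among them) and 3 for the difference, and the block with the signal-level correction gave 4 in F1. The overlap of generations was 0 for called tiles, 5 for the 1000 tiles of smallest p, 10 when a tile within 1 kb counted and 283 for the 10000 of smallest p; longer lists share more by construction. The authors' deposited table has 28 F1 windows at p under 1e-05 and 1 under 1e-07, and 288 and 29 F3 windows, which follows from the threshold. The correlation of fold changes kept its sign in all alternatives, from -0.041 without F1 control pool 1, and with no filter, to -0.211 with a mean count of at least 30. Of the named tiles, F1 tiles kept their side of the threshold in 158 of 158 alternatives, F3 tiles in 140 of 157 and difference tiles in 69 of 105, and none changed direction. In simulated F3 data of the same depth and 3 pools per group, 53 of 100 tiles with a 4-fold change were recovered and 3 of 100 with a 2-fold change. The spread of these simulated data followed the dispersion trend alone, so recovery in the real data may be lower. The planned CpG density correction, alone and with the block, and all promoter and gene list alternatives were not run, as no sequence or annotation of the build was used here.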

Other observations

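The tests of shared profiles, of a continuous gain and of the distance to tiles of high coverage were chosen after the called tiles had been seen. What they would show was not set down beforehand. The fits without both libraries apart in signal level and with the signal-level correction were also added after seeing the data. For these fits, what the correlation of fold changes would show was set down before the result. Across the 12 libraries, the level of the X chromosome fell as that of chromosome 12 rose: Pearson's r was -0.88 (permutation p = 0.00011) and Spearman's rho -0.90 (permutation p = 0.0001). Without the 2 libraries farthest from the median of X, r was -0.77. This was 1 relation picked after looking at the 23 chromosome levels, so the p-values are not adjusted for that choice. The X level ran from 0.682 in F1 control pool 3 to 1.07 in F3 vinclozolin pool 3, and the mitochondrial level from 0.364 in F1 control pool 1 to 10.8 in F1 control pool 3.

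The F3 loci on chromosomes 1, 14 and 5 ranked the F3 pools of each lineage in the same order. In F1, control pool 1 was the highest control pool at each locus. Control pool 3 lay below pool 2 on chromosomes 1 and 14 but above it on chromosome 5. Averaged over called tiles, chromosome 1 had 0.670 ± 0.350 CPM in F3 control and 3.78 ± 1.54 in F3 vinclozolin (SD, n = 3), chromosome 14 had 0.782 ± 0.401 and 3.56 ± 1.36, and chromosome 5 had 1.24 ± 0.552 and 5.01 ± 2.05; at each locus F3 control pool 1 was lowest and F3 vinclozolin pool 2 highest. A candidate explanation is 1 multi-copy sequence whose reads are placed at all 3 loci. In the F1 libraries, which did not choose these tiles, profiles of called tiles on different chromosomes had a median correlation of 0.72, above the 95th percentile of 0.31 for 10000 lists matched on mean count and of 0.53 for such lists of tiles that also lie near high coverage. The 16 tiles belong to only 3 loci, and the lists were not matched on such clustering. Their percentiles can therefore be too easy to exceed, so this comparison does not decide for the multi-copy sequence. For the 3 called tiles outside these loci the same question stays open: their F1 profiles had a median correlation of -0.47 with the loci, but 10.53% of 10000 matched lists lay lower (median 0.02, 95th percentile 0.54), and 3 tiles are too few to decide. Whether the rise is of methylation or of copy number stays open, as input DNA is not analysed here and outbred lineages can differ in copies; this biological difference between lineages was not tested. A continuous gain over each locus cannot be told apart: the other 123 tested tiles inside had a median log2 fold change of 0.49, and 122 were above 0, but they held a median of 626 counts against 68.1 in called tiles, so a fixed gain moves their fold change less, and their median excess in vinclozolin was 4.52 CPM against 3.06. Without F3 control pool 1, 3 of the 19 tiles were called. This met the mark set beforehand for 1 pool deciding the calls, which was under 5 of the 19. All 19 kept their direction, and the leading tiles on chromosomes 1, 14 and 5 moved from log2 fold changes of 3.02, 2.58 and 2.39 to 2.61, 2.30 and 2.03. Most calls were also lost without F3 control pool 3 (6 of the 19 kept) or F3 vinclozolin pool 2 (7 of the 19 kept). The calls thus depend on several pools and not on F3 control pool 1 alone. The lost calls do not show that this pool carries the direction of the rise.

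The negative correlation of F1 and F3 fold changes may reflect how the pools happened to fall into groups. Of 100 pairs of splits of the pools, 38 gave a correlation as large in size as the real one, which was -0.152 for mean differences, and the others ran from -0.271 to 0.258; chance is therefore not excluded. Without F1 control pool 1 and F3 vinclozolin pool 3, whose counts lie more in high tiles, the correlation was -0.107, and with each library's signal-level trend removed it was -0.126, which argues against either as the whole cause. Without F1 control pool 1 alone it was -0.041, and without F1 vinclozolin pool 2 -0.080. The interaction tests whether the effects of the generations differ, not whether they are opposite, and in simulated data it recovered 11 of 100 tiles with a 4-fold change and 0 of 100 with a 2-fold change, so its count says little about an opposite response. It called 0 tiles, 219 without F1 control pool 3 and, with settings chosen after seeing the data, 1113 with the signal-level correction and 982 with that correction and the block; the cause of this rise was not tested.

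For the number of calls, the 10 splits of 6 pools are too few for a share under 0.05. In F1 the real split called 0 tiles and the highest of the others 0; every split meets a count of 0 (10 of 10), so this says nothing about chance. In F3 the real split called 19 and the highest of the others 13, so 1 of 10 splits reached the real count. At an unadjusted p under 0.05, however, the split that put F3 control pool 1 with vinclozolin pools 2 and 3 had 65594 tiles against 56010 in the real one. In F1, 3 other splits had more tiles at an unadjusted p under 0.05 than the real one, with up to 110951 against 34351. Each of the 3 put F1 control pool 1 opposite control pool 3 and vinclozolin pool 2. The shares of counts of these pools in tiles with a mean count of 100 or more were 51.5%, 30.7% and 34.5%. Control pools 1 and 3 share a group in the real split. The cause, and whether this spread lowered the number of F1 calls, was not tested. For the difference the real split also called 0, which all 28 of 28 splits drawn meet, and the highest of the others was 1, so this count says nothing about chance either.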
